A study of Chlorocebus aethiops with 12 samples.

How the data were processed

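Total RNA was taken from COS-1 cells transfected with GR alone or with GR and MDFIC, per the labels. Treatment began 48 h after transfection with vehicle or 100 nM Dex and lasted 6 h, and 3 biological replicates were kept in each of 4 groups. From 500 ng of total RNA, Cy3-labelled RNA was made and hybridised to a one-colour Agilent array with probes for human transcripts, per the labels and the file headers. Each of the 12 arrays gave 1 file with 45015 spots, of which 1639 were control spots. The groups were taken from the labels of each sample.

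The deposited values were intensities on a linear scale. Per the file headers, Agilent Feature Extraction subtracted the background and removed spatial trends to give a processed signal for each spot, with no normalization between arrays. Version 12 is named in the submitters' processing notes, and the file headers give 12.0.0.7 for slides 1 and 2 and 12.0.3.1 for slide 3, which was read on another scanner. The deposited table of the whole series holds the same processed signals (largest difference 0), so its scale is linear and uncentred, and using it changed no result. The deposited flags, other values of 0 or 1 per spot, mark spots that are well above background, saturated or not uniform, per the file headers.

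The processed signal was put on the log2 scale and the 75th percentile of each array's non-control spots was subtracted. Spots with an outlier flag were set to missing (34 values among those tested) and saturated spots were kept. The 41000 probes held 264 printed more than once, whose spots were averaged. A probe was kept where it was well above background on all 3 arrays of at least 1 group and had at least 2 unflagged arrays in each group. Of 30179 probes kept, the one with the highest mean stood for each accession, which left 23757 accessions from 32379, and 5103 of these had several probes past the filter. Probes of 1 accession were called in opposite directions for 2 accessions with Dex in GR cells, 20 with Dex in GR+MDFIC cells, 0 with MDFIC in vehicle, 6 with MDFIC in Dex and 0 in the interaction.

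A group-means model was fitted to the 12 arrays in limma 3.58.1 (R 4.3.3), so that all groups share 1 estimate of the spread with 8 residual degrees of freedom. Dex against vehicle was tested in GR and in GR+MDFIC cells, GR+MDFIC against GR in vehicle and in Dex, and the difference of the Dex effects as the interaction. Tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 counted as a call. Data were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Where a group was not well above background on any array, the fold is a lower bound if the brighter group was well above it on all 3 arrays. It sets the mean of the brighter group against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the dim probe's own signal. Some spots brighter than that lowest signal were not well above background. The bound therefore refers to that signal and not to each probe's own limit of detection. With slide as a fixed block the residual degrees of freedom were 6. The fixed block gives the Dex effects in GR and GR+MDFIC cells as the values within slides 1 and 3, and no slide holds both arms of an MDFIC effect.

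The comparisons, the filter and the alternatives were chosen before the data were examined, apart from leaving out the arrays of slide 3, keeping outlier spots and the ratio of the Dex effects within slides. The rule for named transcripts had called for gene symbols, the 10 largest rises and the 10 largest falls with groups that do not overlap, and members of fixed gene lists, with NR3C1 and MDFIC always given. The files hold accessions with no symbols, and no reference table was used here. It was therefore replaced, after the files were seen, by the 2 largest rises and the 2 largest falls among accessions starting with NM that met the rest of the rule. Named transcripts were thus chosen to have groups that do not overlap. Over all tested transcripts 26.2% for Dex in GR cells, 32.1% for Dex in GR+MDFIC cells, 22.2% for MDFIC in vehicle and 32.1% for MDFIC in Dex had such groups, against 10% by chance. The gene list tests and the check of NR3C1 and MDFIC were not run for the same reason.

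As an alternative, background correction by normexp (offset 50) was combined with quantile scaling, so that both changed together. It used the spot and background medians, since the mean signal it was planned for was not used here. Other alternatives were quantile scaling alone, median scaling, the deposited series table, other filters and the mean of an accession's probes. Slide as a fixed or random block, the replicate number as a block and fits on the compared groups alone were also used. So were an intensity trend combined with robust variance, stricter thresholds, and leaving out each array in turn. Other groupings of the arrays were counted, all 10 for a pairwise comparison and 100 drawn ones for the interaction. The fits were tested on simulated data for 23725 features with known changes. The simulated noise was independent between arrays and held no difference between slides. The shares recovered therefore do not cover the confounding of slides with groups. At a log2 change of 1 they recovered 71.6% for Dex in GR cells, 88.1% for Dex in GR+MDFIC cells, 76.1% for MDFIC in vehicle, 74.6% for MDFIC in Dex and 68.7% for the interaction. At 0.5 the shares were 55.2%, 53.7%, 49.3%, 59.7% and 29.9%. Each share came from 67 changed features in 1 random draw, so differences between the pairwise comparisons may reflect the draw alone. False calls made up 6 of 153, 9 of 167, 6 of 150, 10 of 162 and 10 of 131 calls in the same order.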

Results

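RNA was measured on 12 one-colour arrays of COS-1, a fibroblast-like kidney cell line of the African green monkey. The cells had been transfected with the glucocorticoid receptor (GR), a ligand-activated transcription factor, alone or with MDFIC, the MyoD family inhibitor domain containing protein. They were treated with vehicle or with 100 nM dexamethasone (Dex), a synthetic glucocorticoid that activates GR, for 6 h. Each of the 4 groups held 3 biological replicates. The comparisons addressed how Dex changed transcript levels in cells with GR, and whether MDFIC altered that response. The arrays carry probes designed for human transcripts, so each accession names the human transcript of a probe and not a monkey sequence. The files do not pair accessions with gene names, and transcripts are given by accession. The levels of GR and MDFIC could therefore not be looked up by name as a check of the labels.

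Between 70.3% and 75.2% of the 43376 non-control spots were well above background on each array. The number of arrays limits the precision of every value. Replicates on 1 slide differed by a median of 0.11 on the log2 scale, and the lowest Pearson correlation across probes between replicates on 1 slide was 0.991. The 12 arrays lay on 3 slides. The vehicle replicates of GR cells and 1 Dex replicate shared slide 1, and the other 2 Dex replicates of GR cells shared slide 2 with 2 vehicle replicates of GR+MDFIC cells. Slide 3 held the remaining vehicle replicate and all 3 Dex replicates of GR+MDFIC cells. Its mean 75th percentile signal was 386, against 850 on slide 1 and 868 on slide 2. The first principal component, with 47.0% of the variance, separated the arrays of slide 3 from the others.

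**Figure D1:**
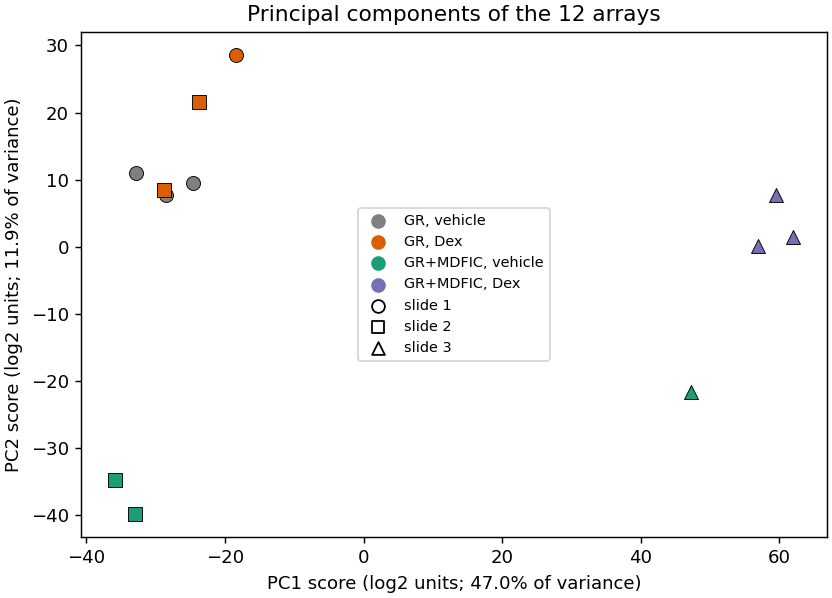
Scores of the 12 arrays on the first 2 principal components of the log2 signals, in log2 units, with 1 point per array, colour for the group and marker shape for the slide. The 4 arrays of slide 3 lie apart on the first component, which holds 47.0% of the variance, and the second holds 11.9%.

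In GR cells, 1038 transcripts rose and 649 fell after 6 h of Dex, among 23757 tested. The transcript NM_000197 rose from a level not well above background on any vehicle array to a measured one on all 3 Dex arrays, at least 11.7-fold. Its mean went from -8.16 ± 0.08 to -2.73 ± 0.11 (log2 relative to the array's 75th percentile, SD, n = 3). NM_199162 likewise rose from not well above background to a measured level, at least 6.23-fold. Among falling transcripts, NM_173538 dropped from -3.89 ± 0.26 to -8.18 ± 0.28 (SD, n = 3), at least 6.32-fold lower, and was not well above background on any Dex array. NM_001042367 was at least 3.15-fold lower. By at least 1 on the log2 scale, 151 transcripts rose and 16 fell. The median size of a call was 0.40 on the log2 scale, against a median standard error of 0.09.

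The limma log2 fold of NM_000197 was 5.43 ± 0.10 (SE) with a Benjamini-Hochberg adjusted p of 7.03e-09, and 5.31 with slide as a block. NM_199162 gave 3.67 ± 0.51 (SE, limma, Benjamini-Hochberg adjusted p = 0.00196) and 3.55 with the block. NM_173538 gave -4.29 ± 0.21 (SE, limma, Benjamini-Hochberg adjusted p = 2.76e-06) and -4.57 with the block. NM_001042367 gave -2.54 ± 0.52 (SE, limma, Benjamini-Hochberg adjusted p = 0.0176). With the block it was -2.67 and no longer passed in limma (Benjamini-Hochberg adjusted p = 0.149, range over the alternatives 0.00214 to 0.149). Its call was also lost without GR vehicle replicate 1 or 2 or GR Dex replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p from 0.0527 to 0.0726). Normexp, which adds an offset of 50 to every signal, was combined with quantile scaling. With both, the log2 folds of NM_000197, NM_199162, NM_173538 and NM_001042367 were 1.36, 0.63, -0.67 and -0.36. A slide block, which uses the arrays of slide 1 alone for this difference and a single Dex array among them, gave 619 that rose and 227 that fell, and 684 transcripts were called in both fits. The count of 1687 was 1118 without GR vehicle replicate 1, 1064 without replicate 3, 1079 without GR Dex replicate 1 and 1085 without GR Dex replicate 2.

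In GR+MDFIC cells, Dex raised 1576 transcripts and lowered 1640. NM_000197 rose again from not well above background to a measured level, from -8.24 ± 0.21 to -2.75 ± 0.10 (SD, n = 3), at least 9.73-fold. NM_016084 rose 15.9-fold between levels measured on every array, from -0.46 ± 0.07 to 3.53 ± 0.04 (SD, n = 3). NM_000639 was measured on 2 of the 3 vehicle arrays, both on slide 2, at -2.81 and -5.14. The vehicle array on slide 3, where all Dex arrays lay, read -6.10 and was not well above background. On the Dex arrays NM_000639 was not well above background, at a computed 3.12-fold lower. That fold is no strict bound, since the vehicle mean includes the undetected array. NM_020526 went from -4.39 ± 0.31 to -7.11 ± 0.52 (SD, n = 3) and was not well above background on any Dex array, at least 3.83-fold lower. A rise of at least 1 on the log2 scale was found for 211 transcripts and a fall of that size for 294.

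NM_000197 gave a limma log2 fold of 5.49 ± 0.10 (SE, Benjamini-Hochberg adjusted p = 6.37e-09) and 5.37 with slide as a block. NM_016084 gave 3.99 ± 0.06 (SE, limma, Benjamini-Hochberg adjusted p = 7.48e-10) and 4.06 with the block, and another probe of the same accession gave 3.73. NM_020526 gave -2.72 ± 0.32 (SE, limma, Benjamini-Hochberg adjusted p = 0.000555) and -2.63 with the block. NM_000639 gave -2.93 ± 0.75 (SE, limma, Benjamini-Hochberg adjusted p = 0.0305), another probe of that accession gave -0.58 and the mean of both probes -1.75. With the block it was -1.51 and did not pass in limma (Benjamini-Hochberg adjusted p = 0.529, range over the alternatives 0.00547 to 0.529). Without GR+MDFIC vehicle replicate 1 it was -2.0, and its call was lost without that array, vehicle replicate 2 or GR+MDFIC Dex replicate 1 or 3 (limma, Benjamini-Hochberg adjusted p from 0.0503 to 0.0994). With normexp and quantile scaling together NM_000197, NM_020526 and NM_000639 gave 1.34, -0.41 and -0.54, and the last no longer passed. The slide block, which here uses slide 3 alone and its single vehicle array, gave 547 that rose and 259 that fell, and 738 were called in both fits. The count of 3216 was 6287 without GR+MDFIC vehicle replicate 3, the only vehicle array on slide 3, and 1817, 1974 and 2125 without GR+MDFIC vehicle replicate 1, vehicle replicate 2 and Dex replicate 3.

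**Figure D2:**
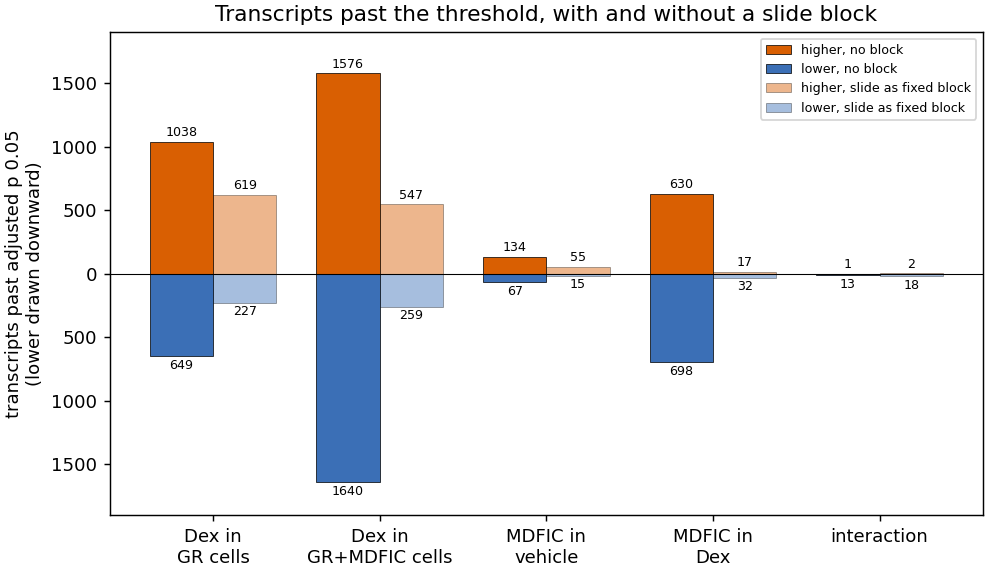
Numbers of transcripts past a limma Benjamini-Hochberg adjusted p of 0.05 for each comparison, higher drawn upward and lower downward, without a block (solid) and with slide as a fixed block (pale). For Dex in GR+MDFIC cells 1576 higher and 1640 lower became 547 and 259 with the block, and for MDFIC with Dex 630 and 698 became 17 and 32.

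The 2 Dex responses overlapped, and they were measured on separate arrays. Both groups of cells shared 856 rising transcripts and 487 falling ones, where independent lists of the same lengths would share 68.9 and 44.8. Another 2 transcripts were called in opposite directions. In the fits with a slide block, 393 rising and 118 falling transcripts were shared, against 14.3 and 2.47. In either fit the 2 responses used the same estimate of the spread per transcript. A transcript with a small spread is then more easily called in both, so independent lists are no strict baseline. NM_016084, measured on all 12 arrays, rose by 3.62 in GR cells and 3.99 in GR+MDFIC cells on the log2 scale, and its other probe by 3.76 and 3.73. NM_000197 and NM_199162 were called in both, but neither was well above background on any vehicle array, so that their rises have only lower bounds and their sizes were not compared. Over the shared transcripts the median ratio of the effect in GR+MDFIC cells to that in GR cells was 1.08 ± 0.04 (jackknife SE), and 1.06 within slides.

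Across the 3558 transcripts called in either response the Pearson correlation was 0.628 and the Spearman correlation 0.713, with transcripts not being independent replicates. Over all tested transcripts they were 0.193 and 0.321. The slope of the GR+MDFIC effect on the GR effect over these 3558 was 0.95 ± 0.58 (jackknife SE). Leaving out an array also redrew the set of transcripts called, so that SE holds the change of set as well. Without GR+MDFIC vehicle replicate 3 the slope was 0.35, over the transcripts called without it. Of the 342 transcripts called in GR cells alone, 306 had the same sign in GR+MDFIC cells, and 2 passed the test of the difference. Of the 1871 called in GR+MDFIC cells alone, 1512 had the same sign in GR cells, and 11 passed that test.

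**Figure D3:**
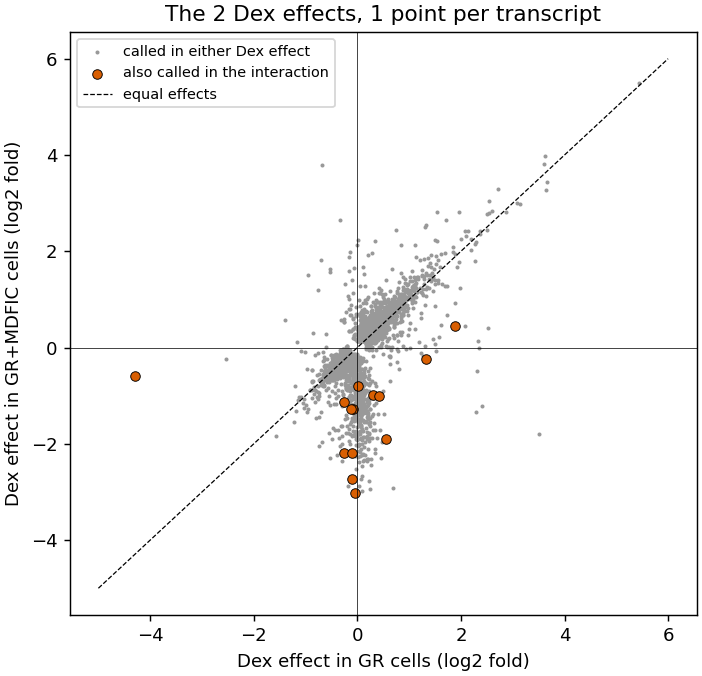
Log2 fold with Dex in GR cells (horizontal) against that in GR+MDFIC cells (vertical), 1 grey point for each of the 3558 transcripts called in either, the 14 called in the interaction in orange, and a dashed line where both are equal. Of the transcripts shown, 1343 were called in both in the same direction.

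In vehicle, GR+MDFIC cells had 134 transcripts higher and 67 lower than GR cells. NM_199072 was 481-fold higher, at 5.68 ± 0.17 against -3.23 ± 0.06 (SD, n = 3), and was measured on all 12 arrays. Another probe of that accession gave a log2 fold of -0.17, and the mean of both probes 4.37. These cells carried the MDFIC construct, whose species the labels do not give, and whether the probe reads RNA from the construct or from the cells' own gene was not determined. NM_014590 was a computed 3.54-fold higher and was well above background on 2 of the 3 GR+MDFIC arrays. Its fold is no strict bound, since the GR+MDFIC mean includes the undetected array. NM_173538 was at least 4.42-fold lower and not well above background in GR+MDFIC cells, the transcript that also fell with Dex in GR cells. Both falls set the same 3 GR vehicle arrays, all on slide 1, against undetected levels, so they are not separate findings. NM_001337 was 5.10-fold lower, from -1.60 ± 0.03 in GR cells to -3.95 ± 0.24 in GR+MDFIC cells (SD, n = 3). It also fell with Dex in GR cells, to -2.80 ± 0.03 (SD, n = 3).

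NM_199072 gave a limma log2 fold of 8.91 ± 0.12 (SE, Benjamini-Hochberg adjusted p = 3.72e-10) and 8.60 with slide as a block. NM_173538 gave -3.80 ± 0.21 (SE, limma, Benjamini-Hochberg adjusted p = 2.79e-05) and -4.02 with the block. NM_001337 gave -2.35 ± 0.12 (SE, limma, Benjamini-Hochberg adjusted p = 2.08e-05) and -2.41 with the block. NM_014590 gave 3.76 ± 0.67 (SE, limma, Benjamini-Hochberg adjusted p = 0.0389). With the block it was 3.07 and did not pass in limma (Benjamini-Hochberg adjusted p = 0.514, range over the alternatives 0.0144 to 0.514). Its call was lost on leaving out any 1 array except GR+MDFIC vehicle replicate 2 and GR+MDFIC Dex replicate 3 (limma, Benjamini-Hochberg adjusted p from 0.054 to 0.131). With normexp and quantile scaling together NM_014590, NM_173538 and NM_001337 gave 0.56, -0.69 and -1.32. With no filter on dim probes NM_014590 gave 1.58, and it passed in neither of these alternatives. The 2 groups share no slide, and a slide block, which links them through slide 2, gave 55 higher and 15 lower, with 34 called in both fits. The count of 201 was 101, 108 and 80 without GR vehicle replicate 1, 2 and 3, 558 without GR+MDFIC vehicle replicate 3, of which 35.8% were higher so that the balance turned, and 131 without GR+MDFIC Dex replicate 3. Without the arrays of slide 3, an alternative added after the data were seen, 222 were called and 50.5% of them were higher, against 66.7% with all arrays.

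With Dex, 630 transcripts were higher and 698 lower in GR+MDFIC than in GR cells. NM_199072 was 339-fold higher, at 5.09 ± 0.20 against -3.31 ± 0.13 (SD, n = 3), so that all 6 arrays of GR+MDFIC cells lay above all 6 of GR cells. NM_014590 was at least 5.11-fold higher. NM_033225 and NM_054032 were at least 2.03-fold and 3.12-fold lower, and neither was well above background on any Dex array of GR+MDFIC cells, all of which lay on slide 3. In GR+MDFIC vehicle, NM_033225 read -5.18 and -4.96 on slide 2 and -7.70 on slide 3. NM_054032 read -4.70, -4.71 and -7.63 in the same order. Neither was well above background on that vehicle array of slide 3, so their lower levels cannot be told apart from a slide difference. The 2 MDFIC effects shared 67 higher and 35 lower transcripts, against 3.55 and 1.97 for independent lists, and 1 was called in opposite directions. In the fits with a slide block they shared 13 higher and 10 lower, with 1 opposite, against 0.0394 and 0.0202. Both groups of GR+MDFIC cells held arrays of slide 3, and both effects used the same estimate of the spread. With the block both effects use the same difference between arrays of slide 2, so their errors are shared. Independent lists are then no fair baseline, and no conclusion is drawn from that overlap.

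NM_199072 gave a limma log2 fold of 8.40 ± 0.12 (SE, Benjamini-Hochberg adjusted p = 6.46e-10) and 8.06 with slide as a block, its other probe -0.24 and the mean of both probes 4.08. NM_014590 gave 3.81 ± 0.67 (SE, limma, Benjamini-Hochberg adjusted p = 0.0245), and with no filter on dim probes another probe stood for it and gave -0.61. With the block it was 3.14 and did not pass in limma (Benjamini-Hochberg adjusted p = 0.761, range over the alternatives 0.00833 to 0.761). NM_033225 gave -2.99 ± 0.60 (SE, limma, Benjamini-Hochberg adjusted p = 0.0307) and NM_054032 gave -2.95 ± 0.67 (SE, limma, Benjamini-Hochberg adjusted p = 0.0394). With the block they were -0.23 and 0.026, and neither passed. With normexp and quantile scaling together NM_014590, NM_033225 and NM_054032 gave 0.65, -0.39 and -0.41. The limma calls of NM_033225 and NM_054032 were lost on leaving out any 1 array of GR vehicle, GR Dex or GR+MDFIC Dex (Benjamini-Hochberg adjusted p up to 0.0885 and 0.106). That of NM_014590 was lost without any 1 GR Dex array or GR+MDFIC Dex replicate 1 or 2 (limma, Benjamini-Hochberg adjusted p from 0.0559 to 0.0795). Under the slide block 17 were higher and 32 lower, and 19 were called in both fits. The count of 1328 was 3111 without GR+MDFIC vehicle replicate 3. It was 566, 517 and 545 without GR vehicle replicate 1, 2 and 3, 111, 116 and 90 without GR Dex replicate 1, 2 and 3, and 293, 380 and 234 without GR+MDFIC Dex replicate 1, 2 and 3. The share of higher calls, 47.4% with all arrays, was 23.2% without GR+MDFIC Dex replicate 2 and 27.3% without GR+MDFIC Dex replicate 1. It was 62.2% without GR Dex replicate 1 and 53.2% with normexp and quantile scaling together, so that neither direction prevailed throughout.

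The test of whether the Dex effect differed between GR+MDFIC and GR cells called 14 of 23757 transcripts, 1 with a higher and 13 with a lower effect in GR+MDFIC cells. NM_182572 was well above background on all 12 arrays and changed by -0.11 with Dex in GR cells and -2.18 in GR+MDFIC cells on the log2 scale. Its means were -2.50 ± 0.11 and -2.62 ± 0.10 in GR cells with vehicle and Dex, and -2.29 ± 0.06 and -4.47 ± 0.15 in GR+MDFIC cells (SD, n = 3). NM_032647 changed by -0.25 with Dex in GR cells and -2.18 in GR+MDFIC cells. NM_173538 was at least 6.32-fold lower with Dex in GR cells. In GR+MDFIC cells it was not well above background with vehicle or with Dex, so a fall there could not have been measured.

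NM_182572 gave a limma interaction of -2.07 ± 0.12 (SE, Benjamini-Hochberg adjusted p = 0.00062) and -2.21 with slide as a block. NM_173538 was called at 3.69 ± 0.30 (SE, limma, Benjamini-Hochberg adjusted p = 0.00427) and 4.37 with the block, but it was not well above background in GR Dex and both GR+MDFIC groups, so this number is no measured size. It did not pass with an intensity trend and robust variance in limma (Benjamini-Hochberg adjusted p = 0.106, range over the alternatives 0.000685 to 0.106). NM_032647 gave -1.93 ± 0.25 (SE, limma, Benjamini-Hochberg adjusted p = 0.046) and with the block -1.84, which did not pass in limma (Benjamini-Hochberg adjusted p = 0.353, range over the alternatives 9.04e-05 to 0.353). Its call was lost on leaving out any 1 array except GR+MDFIC vehicle replicate 3 and GR+MDFIC Dex replicate 2 (limma, Benjamini-Hochberg adjusted p from 0.0594 to 0.172). With normexp and quantile scaling together NM_182572, NM_173538 and NM_032647 gave -1.04, 0.63 and -0.59. The slide block called 20 transcripts, 3 of them among the 14. The count was 1798 without GR+MDFIC vehicle replicate 3, of which 54.2% were higher against 7.14% with all arrays, 95 without GR+MDFIC Dex replicate 2 and 22 without GR+MDFIC Dex replicate 3, and between 2 and 9 without any other array.

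**Figure D4:**
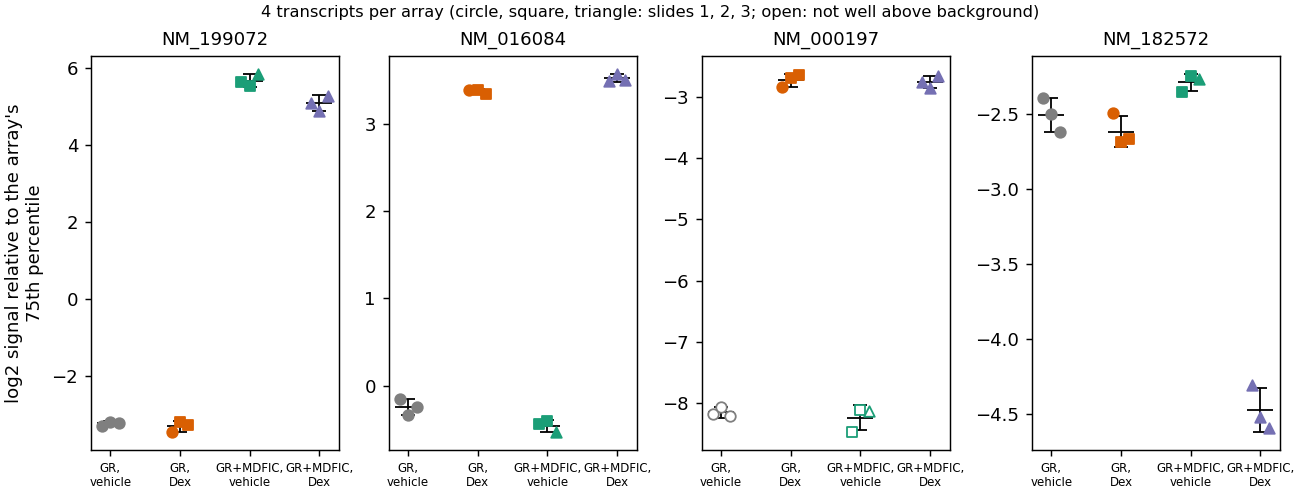
Log2 signal relative to the array's 75th percentile for 4 transcripts, 1 point per array, filled where well above background, with marker shape for the slide and bars for the group mean and SD (n = 3). NM_199072 was high on all 6 GR+MDFIC arrays, NM_016084 and NM_000197 rose with Dex in both kinds of cells, and NM_182572 was lower in the GR+MDFIC cells with Dex (-4.47) than in the other groups.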

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

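The slide and ratio tests, and the test of signals near the background, were chosen after the results had been seen, while the tests of dim probes and of other groupings of the arrays were chosen before. The effect of Dex differed between GR+MDFIC and GR cells for 14 transcripts by the interaction test. Among them NM_182572 had an interaction of -2.07 and NM_032647 of -1.93 on the log2 scale. NM_173538 was called at 3.69, which is no measured size, since 3 of its 4 groups were not well above background on any array. No test for a single array that stands apart was run within the groups of 3. On the first principal component GR+MDFIC vehicle replicate 3 lay at 47.2, against -33.0 and -35.8 for its replicates on slide 2 and 57.0, 61.9 and 59.6 for the other arrays of slide 3, so that it lay with its slide. Without it the vehicle arrays of GR+MDFIC cells are all on slide 2 and the Dex arrays all on slide 3, and the interaction test called 1798 transcripts.

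The 14 transcripts kept a median of 0.971 of their interaction with slide as a block, and the larger errors left 3 of them called. They had been called without a block, where a difference between slides inside a group widens the error. Transcripts with a large slide difference were thus less likely to be among them. The ratio therefore cannot decide whether a difference between slides is the whole cause. A group not well above background was present in 42.9% of the 14 transcripts (6 of 14), against 4.99% of all tested. Signals near the background may therefore account for those 6, NM_173538 among them, while NM_182572 was measured on all arrays. Of 100 groupings of the 12 arrays 5 gave as many calls, the real one included, and the highest of the others gave 2746, so chance cannot be excluded. All 4 others put the 3 GR+MDFIC Dex arrays in the same set and GR+MDFIC vehicle replicate 3, the only vehicle array of slide 3, in the other set. The grouping with 2746 makes the interaction the sum of the 2 MDFIC effects. This points to a structure of the samples. The real count with the slide block was 20. A difference in the Dex response with MDFIC stays open as a hypothesis.

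Without a slide block MDFIC called more transcripts with Dex (1328) than with vehicle (201), but 49 against 70 with slide as a fixed block, 124 against 110 with it as a random block, and 90 to 116 with Dex when any 1 GR Dex array was left out. With the fixed block the effects shrank to a median ratio of 0.417, which argues against MDFIC acting in Dex-treated cells as the whole cause. Across the transcripts called, the effect correlated at 0.898 with GR+MDFIC vehicle replicate 3 on slide 3 minus replicates 1 and 2 on slide 2. Over all tested transcripts, not chosen by the size of the effect, the correlation was 0.740. These vehicle arrays lie outside the comparison in Dex, so a difference between slide 3 and the others may account for much of the count. The fixed block takes out nearly this same difference, so the ratio and the correlation are not separate lines of evidence. Both rest on GR+MDFIC vehicle replicate 3, the only vehicle array of slide 3. Dim probes on the fainter slide cannot be told apart from a difference between slides. Of the calls, 58.6% lay among the dimmest of those tested when these were parted into 3 equal sets, between the bounds set. An action of MDFIC in Dex-treated cells remains open beside the slide, since 19 of the calls were made in both fits.

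Dex called more transcripts in GR+MDFIC cells (3216) than in GR cells (1687), a ratio of 1.91, which was 1.13 in fits on the compared groups alone and 1.16, 1.22 and 3.54 without GR+MDFIC vehicle replicate 1, 2 and 3. With slide as a fixed block the ratio was 0.953, but with slide as a random block it stayed at 1.68 (2533 against 1505), so how far the slides may account for the excess is left open. A larger response to Dex with MDFIC could not be excluded: the median ratio within slides was 1.06, but over transcripts called in both, which are 41.8% of the calls in GR+MDFIC cells. Over all of those calls the median size was 0.41 in GR+MDFIC and 0.23 in GR cells without a block, for transcripts chosen by their size in GR+MDFIC cells.

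For the pairwise comparisons the 10 groupings of 6 arrays are too few for a share under 0.05. The real grouping alone (1 of 10) gave 1687 calls for Dex in GR cells, where the highest other gave 2, and 3216 for Dex in GR+MDFIC cells, where the highest other gave 213. It gave 201 for MDFIC in vehicle, where the highest other gave 2, and 1328 for MDFIC in Dex, where the highest other gave 1.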

How the results depend on the processing

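Leaving out the arrays of slide 3, keeping outlier spots and the within-slide ratio were chosen after the results had been seen. With slide as a fixed block, and equally within slides 1 and 3, Dex called 846 transcripts in GR and 806 in GR+MDFIC cells, with 511 shared, and with that block MDFIC called 70 in vehicle and 49 in Dex. With slide as a random block Dex called 1505 in GR and 2533 in GR+MDFIC cells, MDFIC 110 in vehicle and 124 in Dex, and the interaction 6. Fits on the compared groups alone, with fewer samples, called 1099, 1238, 33 and 2293 for Dex in GR, Dex in GR+MDFIC, MDFIC in vehicle and MDFIC in Dex, with 674 shared by the Dex effects. An intensity trend and robust variance together gave 328 and 2063 for MDFIC in vehicle and Dex and 5 for the interaction. A fold of at least 1.5 left 466, 1067 and 93 for Dex in GR, Dex in GR+MDFIC and MDFIC in vehicle, with 353 shared. An adjusted p under 0.01 left 853, 1352, 57, 59 and 2 for the comparisons in the order of the report, with 721 shared. With no filter on dim probes MDFIC called 114 in vehicle and 867 in Dex. With normexp and quantile scaling together MDFIC called 2339 in Dex, against 1536 with quantile scaling alone. With all 12 arrays above background the interaction called 3. The cause was not tested beyond the slides.

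Leaving out 1 array gave 1064 to 1777 for Dex in GR, 1817 to 6287 for Dex in GR+MDFIC, 80 to 558 for MDFIC in vehicle, 90 to 3111 for MDFIC in Dex, 2 to 1798 for the interaction and 927 to 1368 for the shared transcripts. The slope of the Dex effects, each time over the transcripts called without that array, ranged from 0.35 to 1.02. The highest count in each range, and the lowest slope, came without GR+MDFIC vehicle replicate 3. NM_014590 reversed to -0.61 for MDFIC in Dex with no filter, where another probe stood for it, and NM_054032 to 0.026 with the slide block. In GR+MDFIC vehicle NM_054032 read -4.70 and -4.71 on slide 2, and -7.63 on slide 3, where it was not well above background. A difference between slides may therefore account for that reversal, though this rests on 1 array. The other named results kept their direction, in 428 cases past the threshold and in 86 not, but their sizes moved. With normexp (an offset added to every signal) and quantile scaling, the log2 fold of NM_000197 in GR cells fell to 1.36 from 5.43. That of NM_016084 in GR+MDFIC cells stayed within 3.70 to 4.06 over all alternatives.

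Whether the replicate numbers pair the samples was not settled. Over 18 pairs with the same number the deviations correlated from -0.242 to 0.144, with 3 over 0.1, and 7 arrays correlated best with their own number. The median was 0.028, against -0.008 for pairs with different numbers. In GR Dex and GR+MDFIC vehicle the deviations also hold the difference between slides, so this check cannot exclude a pairing. With the replicate number as a block, MDFIC called 112 in vehicle and the interaction 5. Without the arrays of slide 3, Dex called 1297 in GR cells and MDFIC 222 in vehicle, 93 of them also called with all arrays. Low signal over background limits the named transcripts that are not well above background.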

Other observations

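The split of calls by kind of accession was chosen after the results had been seen. Transcripts with a curated messenger RNA accession, starting with NM, made up 68.0% of those tested. They made up 83.2% of the calls for Dex in GR cells and 76.2% of those for Dex in GR+MDFIC cells. For MDFIC they made up 61.7% of the calls in vehicle and 53.2% in Dex.

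The transcript NM_001337 changed by -1.20 on the log2 scale with Dex in GR cells (limma, Benjamini-Hochberg adjusted p = 0.000329) and by -0.80 in GR+MDFIC cells (limma, Benjamini-Hochberg adjusted p = 0.00272). NM_199072 changed by -0.08 with Dex in GR cells (limma, Benjamini-Hochberg adjusted p = 0.809) and by -0.58 in GR+MDFIC cells (limma, Benjamini-Hochberg adjusted p = 0.0105).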
